A study of Mus musculus with 9 samples.

How the data were processed

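Total RNA of CD19-positive splenic B cells, sorted by flow cytometry from C57BL/6 mice of 5 to 6 weeks, was sequenced with a stranded total RNA kit in 9 libraries, 3 each of WT, Emu-Myc and Emu-Myc Gcn5 Fx/Fx mice. Groups were taken from the genotypes in the labels. The labels do not state whether libraries of a group come from separate animals, nor a litter, day or sequencing batch.

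The deposited files hold read counts per gene, 1 file per library, which the authors made, per the submitters' processing notes, by aligning reads to mm10 with TopHat2 2.0.10 and counting them over genes with HTSeq 0.6.0. The counting mode, the strand setting and the annotation release are not stated, so reads shared between paralogs, pseudogenes or overlapping antisense genes are treated in an unknown way. The values are whole numbers without normalization. Each file has 54055 genes under versioned Ensembl IDs. Of these, 54018 matched a symbol in GENCODE M21 (GRCm38, the assembly also called mm10) by the ID without its version, 52838 had the same version there, and 37 had no match and were kept under their ID.

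Total counts were 26828102, 23537504 and 23747156 in WT 1 to 3, 29825788, 28435238 and 31605341 in Emu-Myc 1 to 3, and 27700193, 29415849 and 27039732 in Emu-Myc Gcn5 Fx/Fx 1 to 3. Genes with low counts were removed with filterByExpr by group, which left 16129. Counts were scaled by TMM and fitted with edgeR 4.0.16 under R 4.3.3 (limma 3.58.1, data.table version 1.17.8, DESeq2 1.42.0) in 1 model of the 3 groups without covariates. The common biological coefficient of variation was 0.219. Each of the 3 comparisons used the quasi-likelihood F test, and genes with a Benjamini-Hochberg adjusted p under 0.05 over all genes tested were called. The SE of a log2 fold change was its size over the square root of F. Principal components were taken from the log2 CPM of all genes tested, with a prior count of 2.

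Gene lists were written from general knowledge, 39 in all with 959 distinct symbols. They cover protein synthesis, metabolism, cell cycle and histones, p53 targets and the BCL2 family, B cell stages, markers of other cell types in spleen, MHC class II, interferon, NF-kB and immediate early genes, SAGA and ATAC subunits, other acetyltransferases and deacetylases, the MYC network, genes of haematopoietic malignancy and sex-linked genes. A list needed 3 measured members. The symbols Rpl40, Mars1, Nars1, Aldoa, Atp5o, Hbb-b1, Hbb-b2 and Ahsp had no match and were left out, so 8 in all. A further 22 symbols were second names of a gene already on the same list, 16 of them aminoacyl-tRNA synthetases, and each gene was counted once. Lists were tested with camera on log2 CPM with the preset correlation of 0.01 between genes, adjusted over the 39 lists of a comparison. Camera with an estimated correlation called 0 lists in each comparison, with a smallest adjusted p of 0.17, 0.369 and 0.172 for Emu-Myc against WT, Emu-Myc Gcn5 Fx/Fx against Emu-Myc and Emu-Myc Gcn5 Fx/Fx against WT, where the preset one called 17 up and 5 down, 5 up and 15 down, and 16 up and 4 down. Fry, which tests whether the genes of a list move on balance in 1 direction (and in its mixed form whether they change in either) and does not compare them with other genes, called 28, 15 and 29. Members were also counted with the adjusted p over all genes and adjusted over the list alone.

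Genes were named by a rule. It took Kat2a, Myc and Cd19, and in each comparison the 10 largest rises and 10 largest falls among called genes with an average log2 CPM of at least 2 and groups that did not overlap, without antigen receptor segments, predicted genes and small RNA genes. It also took up to 4 members with the smallest adjusted p of each list described, and the 10 genes with the smallest larger adjusted p in each of the opposite patterns across the first 2 comparisons. Gm26917 was singled out after its values were seen.

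The overlap of comparisons was set beside the product of the list sizes over the genes tested, and beside 20 simulations of unchanged groups that share libraries in the same way. In a cross-fit, genes were called against WT without 1 Emu-Myc library, and the mean log2 CPM of Emu-Myc Gcn5 Fx/Fx was compared with that library alone.

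The calls were tested on simulated data of 16129 genes with the means, spread and depth of these libraries. Genes changed 1.5-fold, 2-fold and 4-fold were called in 24.2%, 44.4% and 66.2% of cases for Emu-Myc against WT, with 3 false calls of 122. For Emu-Myc Gcn5 Fx/Fx against Emu-Myc these were 25.7%, 61.4% and 76.7%, with 6 of 135, and for Emu-Myc Gcn5 Fx/Fx against WT 24.6%, 55.2% and 85.3%, with 11 of 147. Few genes were changed in each simulation, for Emu-Myc against WT 66, 63 and 71 at these sizes plus 1 gene list. The real comparison called 49.4% of genes, and the adjusted p depends on the share changed, so these percentages may understate recovery in it.

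The alternatives were DESeq2, limma-voom, size factors of the DESeq2 type (RLE) and total counts in place of TMM, no filter on low counts, a strict filter (at least 10 counts in 3 libraries and an average log2 CPM of at least 1), a fit of the 2 groups compared alone, the replicate number as a block, each library left out in turn, and a log2 fold change of at least 1 beside the adjusted p. Chosen after the data were seen were a term for Emu-Myc 1, Emu-Myc 2 and WT 1, leaving these 3 libraries out (Emu-Myc then has 1 library, assumed to vary like the other groups), and not counting antigen receptor segments. To test explanations, the macrophage and pro-B lists were also fitted over all 9 libraries with that term and a term for sex. This fit was likewise chosen after the data were seen. The 2 male libraries had Ddx3y above 1 CPM by total counts.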

Results

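Total RNA was sequenced from splenic B cells, sorted by flow cytometry for the B cell surface protein CD19, of C57BL/6 mice aged 5 to 6 weeks. The 9 bulk libraries fall into 3 groups of 3. The labels give WT mice as wild type, without further genotype. Emu-Myc mice carried a Myc transgene driven by the immunoglobulin heavy chain enhancer, which expresses Myc in B cells and leads to B cell lymphoma, and per the labels had 1 floxed copy of Gcn5 and no Cre. Emu-Myc Gcn5 Fx/Fx mice (below, Gcn5 Fx/Fx) carried the same transgene, floxed Gcn5 on both copies and a CD19 Cre transgene. Gcn5 is the protein of the gene Kat2a, a histone acetyltransferase that serves the SAGA and ATAC coactivator complexes. Cre and the second floxed copy differ together between the Myc groups, so no comparison here separates them. The labels do not say whether libraries of a group come from separate animals, so each p-value measures spread between samples.

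The values are read counts per gene. Total counts per library ran from 23537504 (WT 2) to 31605341 (Emu-Myc 3). Levels are given as CPM (counts scaled to the TMM-normalised size of the library) with the SD over the 3 libraries of a group. After the filter on low counts 16129 genes were tested. Gene calls are those with an adjusted p under 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. A permutation test of 3 against 3 libraries cannot give a p below 0.1, so none is given for single genes.

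The first principal component of the log2 CPM values (48.3% of the variance) separated WT, at 76.0 to 79.8, from the 6 Myc libraries, at -62.0 to -19.5. The second component (26.7%) set 3 libraries of 2 groups apart: Emu-Myc 1 at 56.6, Emu-Myc 2 at 53.4 and WT 1 at 55.9, against -60.4 to -3.4 in the other 6. The same 3 libraries held the highest levels of the macrophage and monocyte list, which was fixed before the data were examined, as were the other lists, the edgeR and camera tests over all 9 libraries and the rule for naming genes. Its 19 measured members summed to 763 CPM in Emu-Myc 1, 1113 CPM in Emu-Myc 2 and 425 CPM in WT 1, against 37.3 to 84.9 CPM elsewhere. The share of counts on the predicted gene Gm26917 was also highest there, at 6.19%, 6.19% and 3.70% against 0.714% to 2.13%. What these reads come from was not tested.

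**Figure D1:**
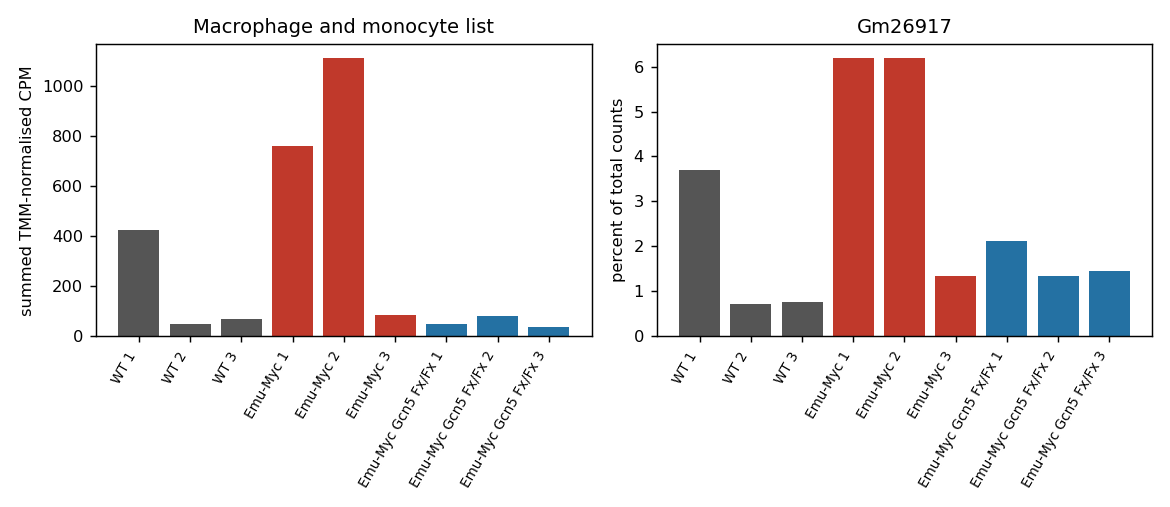
Summed TMM-normalised CPM of the 19 measured macrophage and monocyte genes (left) and share of total counts on Gm26917 (right), 1 bar per library, coloured by group. WT 1, Emu-Myc 1 and Emu-Myc 2 stand above the other 6 libraries in both panels.

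Kat2a RNA, the targeted transcript, was higher in B cells with the Myc transgene and lower again with Gcn5 Fx/Fx. Kat2a (ENSMUSG00000020918.14, chromosome 11, 100704746 to 100712465, GRCm38) stood at 52.8, 52.45 and 52.2 CPM in WT, at 110, 112 and 120 CPM in Emu-Myc and at 67.5, 64.1 and 73.1 CPM in Gcn5 Fx/Fx. The group means were 52.5 ± 0.31, 114 ± 5.41 and 68.2 ± 4.55 CPM (SD, n = 3), and no libraries of different groups overlapped. The log2 fold change was 1.12 (SE 0.07) from WT to Emu-Myc and -0.74 (SE 0.07) from Emu-Myc to Gcn5 Fx/Fx, with adjusted p = 2.4e-06 and 0.000755 by edgeR's quasi-likelihood test. Gcn5 Fx/Fx remained above WT by 0.38 (SE 0.07, edgeR adjusted p = 0.0021). The counts cover the whole gene, including any exons outside the floxed part, so they do not measure how much intact transcript was left.

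Myc (ENSMUSG00000022346.15, chromosome 15, 61985391 to 61990374), the transcription factor the transgene encodes, rose 11.2-fold from 76.8 ± 12.7 CPM in WT to 858 ± 39.7 CPM in Emu-Myc (SD, n = 3), with an edgeR adjusted p of 3.05e-07. Gcn5 Fx/Fx held 667 ± 34.6 CPM, a log2 difference of -0.36 (SE 0.11) from Emu-Myc that did not pass the threshold (edgeR adjusted p = 0.0558). It passed with DESeq2 (adjusted p = 0.00977), limma-voom (0.0427), an edgeR fit of the 2 groups alone (0.0299), a block for the replicate number (0.0487) and without WT 1 (0.0133). With a term for Emu-Myc 1, Emu-Myc 2 and WT 1 in the edgeR fit the difference was -0.21 (adjusted p = 0.24), and without these libraries -0.31 (0.129). Cd19 (ENSMUSG00000030724.7, chromosome 7, 126408450 to 126414889), the antigen used for the sort, was at 973 ± 105 CPM in WT and 833 ± 110 CPM in Emu-Myc, which overlapped (edgeR adjusted p = 0.191). In Gcn5 Fx/Fx it stood at 451 ± 66.9 CPM, a log2 difference of -0.89 (SE 0.14) from Emu-Myc and -1.11 (SE 0.14) from WT (edgeR adjusted p = 0.00428 and 0.000145). Per the labels only this group carried the CD19 Cre, and they do not say whether its allele disrupts a copy of Cd19, so the counts do not separate a disrupted copy from lower expression of Cd19.

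**Figure D2:**
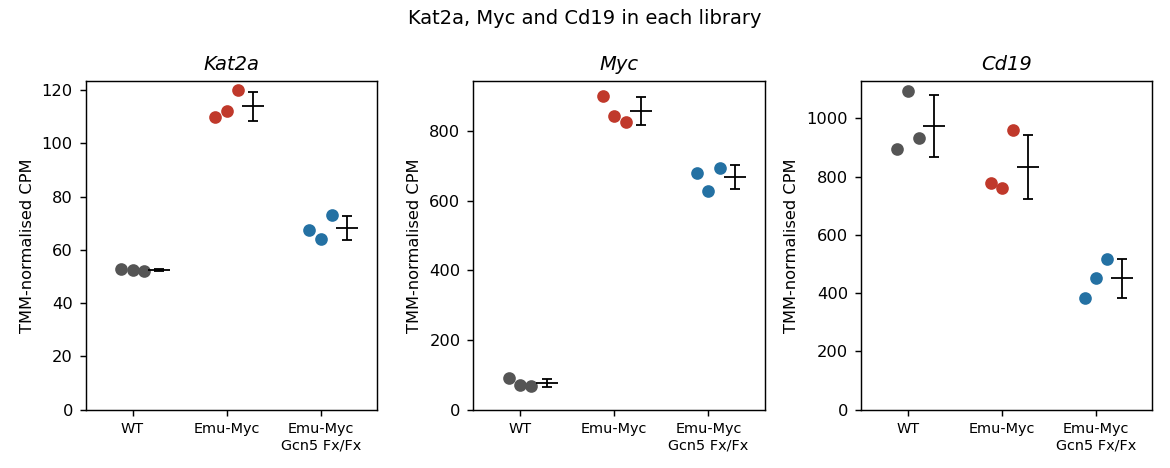
TMM-normalised CPM of Kat2a, Myc and Cd19 in the 3 libraries of each group (points) with group mean and SD (bars at right of the points). Kat2a lies at 52.2 to 52.8 in WT, 110 to 120 in Emu-Myc and 64.1 to 73.1 in Gcn5 Fx/Fx.

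The comparison of Emu-Myc with WT asks which genes go with the Myc transgene. Emu-Myc B cells held more RNA for making ribosomes, for building blocks of growth and for dividing, and less of mature B cell genes. These list calls were made by camera with the preset correlation and not with an estimated one. Cdk1, the kinase that starts mitosis, rose 42.9-fold to 47.1 ± 17.6 CPM from 1.10 ± 0.28 CPM (SD, n = 3). Rag1, which recombines antigen receptor genes in developing lymphocytes, rose 53.8-fold to 166 ± 5.97 CPM from 3.08 ± 1.04 CPM. Cr2 (CD21), the complement receptor of mature B cells, fell from 1045 ± 63.2 to 117 ± 21.7 CPM, and Fcer2a (CD23), the low-affinity IgE receptor, from 708 ± 97.8 to 67.0 ± 7.68 CPM. The edgeR adjusted p-values of these 4 genes lay between 8.64e-07 and 1.68e-05.

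Of 16129 genes, 4340 were higher and 3626 lower in Emu-Myc, which is 49.4% of those tested, and 2005 and 1507 of them changed at least 2-fold. Scaling by total counts alone moved the median of all genes by -0.18 (log2) and gave 3308 higher and 4918 lower genes, so that the share of higher calls went from 54.5% to 40.2%. Changes are therefore relative to the TMM scale. With a term for Emu-Myc 1, Emu-Myc 2 and WT 1 in the edgeR fit there were 4724 higher and 4115 lower genes, of which 4286 and 3481 were the same genes as without it. Without these 3 libraries there were 3761 and 2677, sharing 3526 and 2393. Both settings were chosen after the data were seen. The second leaves 1 Emu-Myc library, Emu-Myc 3. Its Y-linked gene Ddx3y was at 102 CPM by total counts, against at most 0.04 CPM in Gcn5 Fx/Fx, WT 2 and WT 3. Sex and genotype are therefore confounded in the comparisons with Emu-Myc in this setting. The 10 largest rises among genes with libraries that did not overlap were Hspa12b of the Hsp70 family, the histone genes Hist1h2ah and Hist1h3g, the carbonic anhydrase Car12, Tmem132e, Rag1, Ltbp4, the ubiquitin hydrolase Uchl1, Cdk1 and the nucleotide hydrolase Dnph1. Their log2 fold changes ran from 6.74 (Hspa12b, SE 0.47) to 5.36 (Dnph1, SE 0.41), with edgeR adjusted p up to 5.37e-05. The 10 largest falls ran from -5.13 (Ptpn14, a tyrosine phosphatase, SE 0.29) to -3.07 (Lta, lymphotoxin alpha, SE 0.26). Between them lay the MAP kinase phosphatase Dusp4, the receptor Gpr174, Eya1, Fcer2a, the costimulatory ligand Icosl, the actin-severing protein Gsn, Cr2 and Gad1, with edgeR adjusted p up to 7e-05. By chance, 10% of genes have groups of 3 and 3 that do not overlap.

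Genes of protein synthesis rose as groups in Emu-Myc. All 39 measured genes of ribosome biogenesis were higher (39 adjusted over the list alone), with a median log2 fold change of 1.25 and a camera adjusted p of 8.64e-18, or adjusted p = 0.17 with an estimated correlation. Npm1, a nucleolar chaperone of ribosome assembly, rose from 379 ± 11.3 to 1621 ± 126 CPM, and Dkc1, which modifies ribosomal RNA, from 73.3 ± 2.12 to 286 ± 16.1 CPM (SD, n = 3). Of 78 cytosolic ribosomal protein genes 74 were higher (74 adjusted over the list alone, median 1.04, camera adjusted p = 2.24e-20 and adjusted p = 0.298 with an estimated correlation). Rpl13a rose by 1.52 and Rpl28 by 1.5 in log2, though reads of this family can be shared with its processed pseudogenes. All 26 translation factors rose (26 adjusted over the list alone, median 1.02, camera adjusted p = 3.18e-12 and adjusted p = 0.17 with an estimated correlation), among them Eef1g at 1.41 and Eif5a at 1.74. Of 20 aminoacyl-tRNA synthetases 18 were higher (18 adjusted over the list alone, median 0.66, camera adjusted p = 2.58e-06 and adjusted p = 0.303 with an estimated correlation). Mitochondrial ribosomal proteins were higher for 42 of 45 genes (43 adjusted over the list alone, median 0.71, camera adjusted p = 1.84e-11 and adjusted p = 0.301 with an estimated correlation).

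Metabolic genes rose with them. All 27 genes of nucleotide synthesis were higher (27 adjusted over the list alone, median 1.5, camera adjusted p = 2.3e-12 and adjusted p = 0.245 with an estimated correlation), including Atic, a purine synthesis enzyme, at 288 ± 10.2 against 97.4 ± 2.65 CPM (SD, n = 3). For amino acid and one-carbon metabolism the count was 25 of 26 (25 adjusted over the list alone, median 1.40, camera adjusted p = 5.33e-12 and adjusted p = 0.17 with an estimated correlation), with Phgdh, which opens serine synthesis, at 345 ± 40.3 against 70.3 ± 3.24 CPM. Protein folding chaperones rose in 26 of 27 cases (26 adjusted over the list alone, median 1.24, camera adjusted p = 9.2e-12 and adjusted p = 0.17 with an estimated correlation), and oxidative phosphorylation in 36 of 37 (37 adjusted over the list alone, median 0.88, camera adjusted p = 3.18e-12 and adjusted p = 0.304 with an estimated correlation). Glycolysis was mixed, with 11 higher and 3 lower of 19 (11 and 3 adjusted over the list alone, median 0.85, camera adjusted p = 0.00363 and adjusted p = 0.298 with an estimated correlation). Slc16a1, the lactate transporter, rose by 3.01 and Ldha, lactate dehydrogenase A, by 1.80 in log2.

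Mitosis and histone genes had the 2 largest list medians. Mitosis genes had a median log2 fold change of 4.14, with 37 higher and 1 lower of 39 (38 and 1 adjusted over the list alone, camera adjusted p = 3.04e-15 and adjusted p = 0.303 with an estimated correlation). Top2a, the topoisomerase that untangles chromosomes, rose from 22.8 ± 0.99 to 605 ± 188 CPM, and the spindle motor Kif11 from 4.38 ± 0.78 to 168 ± 45.6 CPM (SD, n = 3). DNA replication genes were higher in 35 of 38 cases (35 adjusted over the list alone, median 1.70, camera adjusted p = 3.18e-12 and adjusted p = 0.306 with an estimated correlation), and G1/S and E2F genes in 21 of 24, with 2 lower (21 and 2 adjusted over the list alone, median 1.91, camera adjusted p = 7.12e-08 and adjusted p = 0.245 with an estimated correlation). Cdc6, which loads the replicative helicase, rose by 4.58 and the repressor E2f7 by 4.58 in log2. All 28 replication-dependent histone genes were higher (28 adjusted over the list alone, median 2.67, camera adjusted p = 3.19e-13 and adjusted p = 0.245 with an estimated correlation). Near-identical histone copies can share reads, so single histone genes are uncertain. Of 26 p53 targets 17 were higher and 3 lower (17 and 3 adjusted over the list alone, median 0.67, camera adjusted p = 0.00119 and adjusted p = 0.17 with an estimated correlation), among them the death activator Bbc3 (Puma) at 3.14. The MYC network list, which holds Myc itself, had 7 higher and 2 lower of 15 (8 and 2 adjusted over the list alone, median 0.44, camera adjusted p = 0.0193 and adjusted p = 0.17 with an estimated correlation), with a median of 0.28 under the term for Emu-Myc 1, Emu-Myc 2 and WT 1 and 0.16 without them.

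B cell stage genes moved in opposite directions. Genes of pro-B and pre-B cells, the marrow precursors, were higher in 14 and lower in 1 of 19 (15 and 1 adjusted over the list alone, median 2.22, camera adjusted p = 9.1e-05 and adjusted p = 0.291 with an estimated correlation). Sox4, a transcription factor of early B cells, rose from 29.2 ± 4.67 to 136 ± 12.8 CPM and Myb from 23.8 ± 3.84 to 132 ± 21.1 CPM (SD, n = 3). Mature B cell genes were lower in 25 of 29 cases (26 adjusted over the list alone, median -1.41, camera adjusted p = 3.18e-12 and adjusted p = 0.17 with an estimated correlation). The inhibitory receptor Btla fell from 705 ± 19.7 to 219 ± 7.08 CPM and Icosl from 354 ± 42.5 to 36.0 ± 6.25 CPM. Antigen presentation by MHC class II fell in 19 of 21 genes (19 adjusted over the list alone, median -0.86, camera adjusted p = 2.96e-08 and adjusted p = 0.245 with an estimated correlation), including its master regulator Ciita at -1.23. NF-kB targets fell in 14 of 17 (14 adjusted over the list alone, median -1.15, camera adjusted p = 3.77e-08 and adjusted p = 0.17 with an estimated correlation), with Nfkb2 at -1.59 and Relb at -1.40. The interferon response list had 10 lower of 25 (10 adjusted over the list alone, median -0.76, camera adjusted p = 0.005 and adjusted p = 0.588 with an estimated correlation). That call was lost without Emu-Myc 1, Emu-Myc 2 and WT 1 (median -0.49, camera adjusted p = 0.0754) and kept with a term for them (-0.47, 0.018, and 0.427 with an estimated correlation). The pan-B and B cell receptor list had 2 higher and 12 lower of 25 (2 and 12 adjusted over the list alone, median -0.34, camera adjusted p = 0.0138 and adjusted p = 0.218 with an estimated correlation).

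The other lists did not pass the threshold under camera in this comparison. Counts of higher and lower genes were 2 and 0 of 19 for macrophages and monocytes (1 and 0 adjusted over the list alone, median 1.96, camera adjusted p = 0.0637), whose levels were high in WT 1, Emu-Myc 1 and Emu-Myc 2. With the term for these 3 libraries the macrophage list passed, with 12 of 19 higher and a median of 0.99 (camera adjusted p = 0.0235, and 0.625 with an estimated correlation), and without them it did not (0.59, 0.137). Counts were 7 and 3 of 15 for the BCL2 family (camera adjusted p = 0.596), 1 and 4 of 12 for germinal centre B cells (0.245), 7 and 1 of 14 for plasma cells (0.168) and 5 and 4 of 12 for marginal zone and B1 cells (0.792), each with the same counts adjusted over the list alone. T cells gave 2 and 1 of 23 (0.979, median -0.14 while camera's direction was up), NK cells 1 and 1 of 11 (0.897), neutrophils 0 and 0 of 13 (0.596), dendritic cells 1 and 0 of 10 (0.73) and erythroid cells 1 and 1 of 10 (0.426). Megakaryocytes gave 1 and 2 of 5 (0.395, median 0.05 while camera's direction was down), stroma and endothelium 1 and 1 of 6 (0 and 1 adjusted over the list alone, 0.972) and immediate early genes 3 and 9 of 23 (4 and 10 adjusted over the list alone, 0.107). The SAGA and ATAC complexes had 13 and 6 of 31 (0.195), other acetyltransferases and deacetylases 5 and 6 of 22 (0.916, median -0.03, mean 0.03, direction down), genes of haematopoietic malignancy 8 and 6 of 19 (0.596) and sex-linked genes 0 and 0 of 3 (0.948, median -0.17, mean 0.16, direction down). Without Emu-Myc 1, Emu-Myc 2 and WT 1 germinal centre B cells (camera adjusted p = 0.0474), immediate early genes (0.0457) and sex-linked genes (0.0173) passed, with adjusted p = 0.343, 0.525 and 0.269 with an estimated correlation. The medians of NK cells (from 0.63 to -1.03), dendritic cells (0.75 to -0.86), erythroid cells (1.30 to -0.47), megakaryocytes (0.05 to -1.76), stroma and endothelium (0.78 to -0.25) and sex-linked genes (-0.17 to 6.17) changed sign there. With the term those of NK cells (-0.06), neutrophils (-0.05, from 0.96), dendritic cells (-0.10) and megakaryocytes (-0.88) did.

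**Figure D3:**
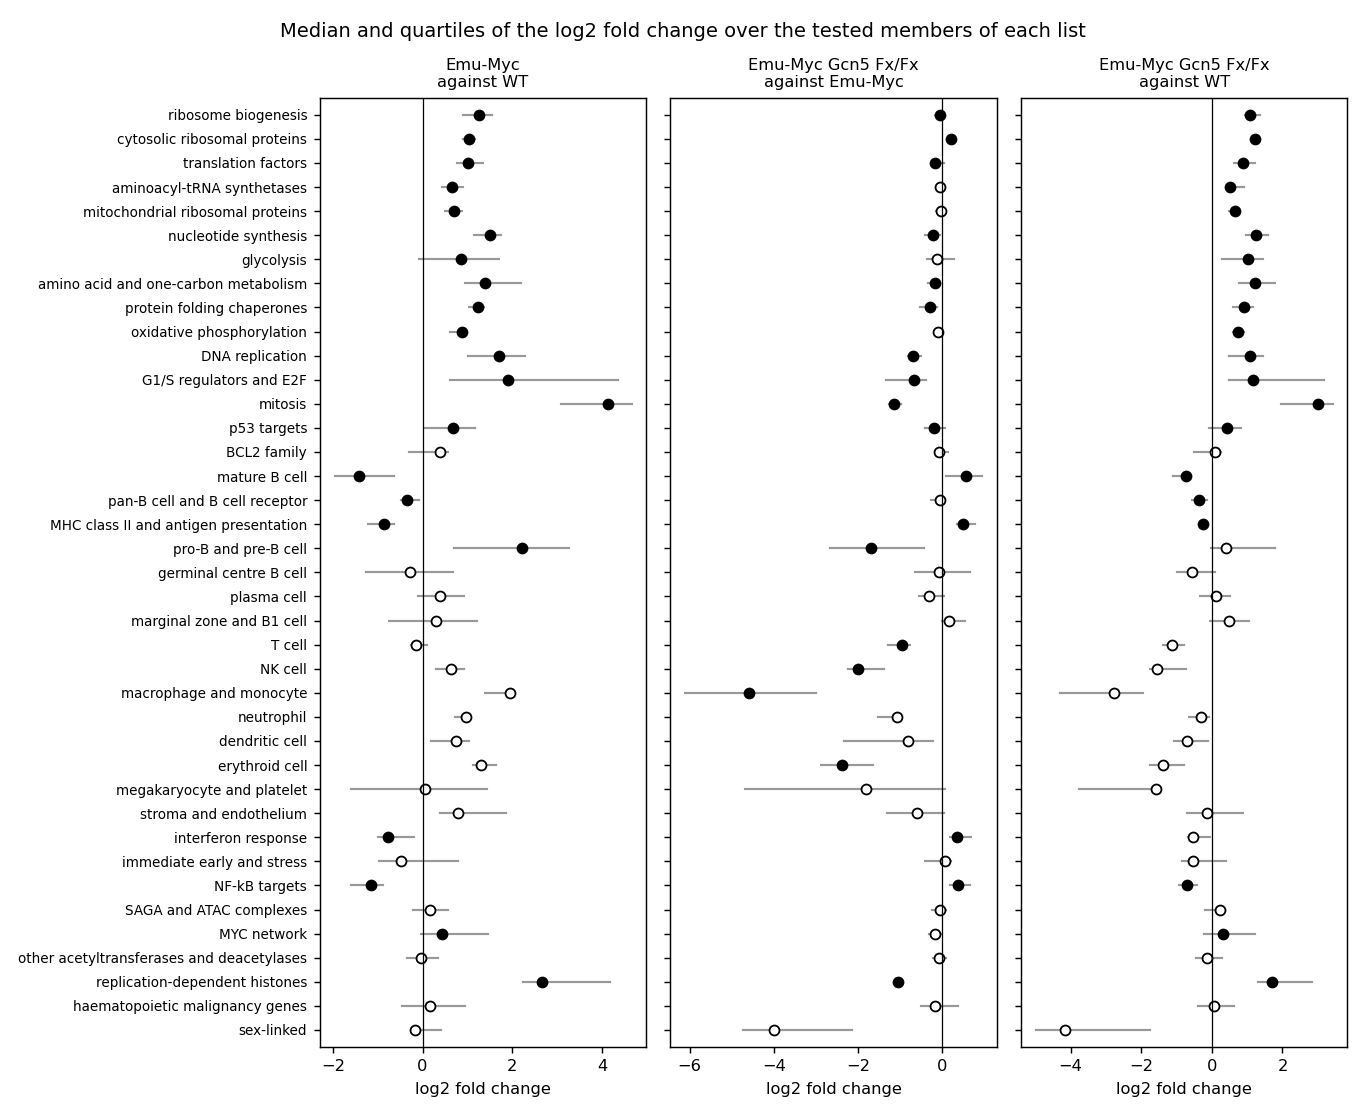
Median log2 fold change (points) and quartiles (lines) over the measured members of each of 39 gene lists, in 3 comparisons with their own horizontal scales. Filled points have a camera adjusted p under 0.05 with the preset correlation, and none does with an estimated one. Mitosis has medians of 4.14, -1.14 and 3.01 from left to right.

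The comparison of Gcn5 Fx/Fx with Emu-Myc asks which genes depend on the Gcn5 genotype, together with Cre, when Myc is overexpressed. Gcn5 Fx/Fx B cells held less RNA of early B cell genes, of cell division and of histones, and more of mature B cell, MHC class II and NF-kB genes. As lists these passed under camera with the preset correlation and not with an estimated one. Rag1 fell from 166 ± 5.97 to 12.8 ± 10.48 CPM and Sox4 from 136 ± 12.8 to 33.7 ± 5.45 CPM (SD, n = 3). Il9r, the interleukin 9 receptor, rose 10.6-fold from 9.35 ± 0.94 to 98.8 ± 22.2 CPM, and Bcl2, which blocks cell death, rose 2.22-fold from 52.3 ± 2.78 to 116 ± 13.1 CPM. The edgeR adjusted p-values of these 4 genes lay between 0.000298 and 0.00186.

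In all, 1227 genes were higher and 1098 lower (14.4% of 16129), with 382 and 484 at least 2-fold apart. Scaling by total counts gave 1324 higher and 763 lower genes, which moved the share of higher calls from 52.8% to 63.4%. Leaving out 1 library moved these counts: without Emu-Myc 2 there were 473 higher and 267 lower genes, without Gcn5 Fx/Fx 1 there were 529 and 298, without Emu-Myc 1 there were 755 higher, and without Gcn5 Fx/Fx 2 and 3 there were 727 and 513 lower. With the term for Emu-Myc 1, Emu-Myc 2 and WT 1 there were 900 higher and 1066 lower genes (721 and 761 shared), and without these libraries 621 and 750 (474 and 567 shared). The largest rises after Il9r (3.40, SE 0.24) were Eya1, the transporters Abcb9 and Abca5, the protease inhibitor Serpina3g, the pyrophosphate transporter Ank, the cadherin Cdh17, Lurap1, Setbp1 and the inactive rhomboid Rhbdf1 (2.00, SE 0.22), with edgeR adjusted p up to 0.0186. Abca5 (2.42) lost its call with a term for Emu-Myc 1, Emu-Myc 2 and WT 1 (1.86, edgeR adjusted p = 0.0798), without Emu-Myc 2 (2.04, 0.056) and without Gcn5 Fx/Fx 1 (2.16, 0.0729).

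The 10 largest falls were Mertk, Vcam1, C1qb, Fcna, Ccr3, C1qc, Itgad, Cd163, Abcc3 and C1qa, with log2 fold changes from -7.53 (Mertk, SE 1.66) to -6.43 (C1qa, SE 1.49) and edgeR adjusted p up to 0.0298. Several of them are known macrophage genes, such as the complement components of C1q and the engulfment receptor Mertk. Vcam1 stood at 106 ± 87.3 CPM in Emu-Myc, 25.8 ± 39.1 CPM in WT and 0.82 ± 0.42 CPM in Gcn5 Fx/Fx (SD, n = 3). On the macrophage and monocyte list 13 of 19 genes were lower (16 adjusted over the list alone, median -4.60, camera adjusted p = 2.9e-07 and adjusted p = 0.501 with an estimated correlation). The list's summed level was 763, 1113 and 84.9 CPM in Emu-Myc 1 to 3 and 51.5, 80.3 and 37.3 CPM in Gcn5 Fx/Fx 1 to 3. With Emu-Myc 1, Emu-Myc 2 and WT 1 left out, 7 of 18 genes were lower and the median was -1.33 (camera adjusted p = 4.05e-06, and 0.431 with an estimated correlation), and with the term for them it was -1.68 (4.05e-08, and 0.382 with an estimated correlation). The 10 largest falls were smaller in these 2 settings, at -4.10 (Mertk) to -2.51 (Cd163) with the term and -4.28 (Mertk) to -1.77 (Cd163) without these libraries. Calls among the 10 largest falls were lost in 10 cases without Gcn5 Fx/Fx 1 (edgeR adjusted p up to 0.118), 9 without Gcn5 Fx/Fx 3 (0.0925), 6 without Emu-Myc 2 (0.0801), 5 without Gcn5 Fx/Fx 2 (0.0656) and 1 without Emu-Myc 1 (0.0542). The log2 fold changes of these lost calls ran from -8.16 (Cd163, without Gcn5 Fx/Fx 2) to -5.81 (C1qa, without Emu-Myc 2). With limma-voom all 10 were lost (adjusted p from 0.135 to 0.29), with log2 fold changes from -6.53 (Mertk) to -5.66 (Cd163). Cd163 was also lost with the term for these 3 libraries (edgeR adjusted p = 0.0646), and Cd163 and Abcc3 without them (0.291 and 0.0686).

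Early B cell genes fell and mature B cell genes rose. On the pro-B and pre-B list 11 of 19 genes were lower (12 lower and 1 higher adjusted over the list alone, median -1.69, camera adjusted p = 1.85e-06 and adjusted p = 0.369 with an estimated correlation). Rag2, the partner of Rag1, stood at 8.03 ± 1.88 CPM in Emu-Myc, 0.45 ± 0.15 CPM in Gcn5 Fx/Fx and 0.09 ± 0.08 CPM in WT (SD, n = 3). Myb fell from 132 ± 21.1 to 33.99 ± 10.6 CPM, near the 23.8 ± 3.84 CPM of WT. The mature B cell list had 16 higher and 2 lower of 29 (17 and 3 adjusted over the list alone, median 0.55, camera adjusted p = 4.62e-07 and adjusted p = 0.369 with an estimated correlation), with the migration receptor Gpr183 at 1.46, the chemokine receptor Ccr6 at 1.43 and Icosl at 1.29 in log2. MHC class II and antigen presentation genes were higher in 15 of 21 cases (20 adjusted over the list alone, median 0.49, camera adjusted p = 6.92e-11 and adjusted p = 0.369 with an estimated correlation). H2-Oa, a modulator of peptide loading, rose from 74.2 ± 2.13 to 173 ± 27.3 CPM and H2-DMa, which loads peptides, from 167 ± 5.94 to 292 ± 42.7 CPM. NF-kB targets rose in 11 of 17 (12 adjusted over the list alone, median 0.38, camera adjusted p = 2.51e-07 and adjusted p = 0.369 with an estimated correlation), with Ltb (lymphotoxin beta) at 1.36 and Traf1 at 1.00.

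Cell cycle genes were lower as lists in Gcn5 Fx/Fx than in Emu-Myc. Mitosis genes fell in 31 of 39 cases (38 adjusted over the list alone, median -1.14, camera adjusted p = 4.82e-13 and adjusted p = 0.501 with an estimated correlation). Cdc25b, a phosphatase that activates Cdk1, fell from 133 ± 18.6 to 82.0 ± 7.24 CPM and the spindle checkpoint gene Mad2l1 from 42.8 ± 8.94 to 22.0 ± 4.51 CPM (SD, n = 3). DNA replication genes fell in 24 of 38 (35 adjusted over the list alone, median -0.69, camera adjusted p = 1.87e-12 and adjusted p = 0.501 with an estimated correlation), including Orc1 of the origin recognition complex at -1.19 and Cdc6 at -1.33. G1/S and E2F genes fell in 15 of 24 (21 adjusted over the list alone, median -0.67, camera adjusted p = 5.27e-09 and adjusted p = 0.369 with an estimated correlation), among them E2f7 at -1.41 and cyclin E2 (Ccne2) at -1.57. Replication-dependent histone genes fell in 23 of 28 (27 adjusted over the list alone, median -1.05, camera adjusted p = 1.87e-12 and adjusted p = 0.369 with an estimated correlation), such as Hist1h3b from 146 ± 49.4 to 43.5 ± 11.98 CPM. The p53 targets had 5 lower of 26 (6 lower and 1 higher adjusted over the list alone, median -0.20, camera adjusted p = 0.0259 and adjusted p = 0.369 with an estimated correlation), with the kinase Plk2 at -1.02. That call was lost without Emu-Myc 2 (camera adjusted p = 0.0938), without Gcn5 Fx/Fx 2 (0.062), without WT 1 (0.0533), with the strict filter on low counts (0.0756) and with Emu-Myc 1, Emu-Myc 2 and WT 1 left out together (0.0875).

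Lists of growth genes had medians from -0.29 to 0.20. Protein folding chaperones were lower in 9 of 27 cases (11 adjusted over the list alone, median -0.29, camera adjusted p = 3.75e-06 and adjusted p = 0.369 with an estimated correlation), with Cct7 of the chaperonin ring at -0.47. Nucleotide synthesis had 8 lower of 27 (10 adjusted over the list alone, median -0.22, camera adjusted p = 0.00127 and adjusted p = 0.611 with an estimated correlation), with Umps at -0.46. Amino acid and one-carbon metabolism had 5 lower of 26 (5 adjusted over the list alone, median -0.17, camera adjusted p = 0.00305 and adjusted p = 0.576 with an estimated correlation), with the transaminase Bcat1 at -1.59. That list's call was lost without Emu-Myc 3 (0.0561). Translation factors had 2 lower of 26 (6 adjusted over the list alone, median -0.17, camera adjusted p = 0.0169 and adjusted p = 0.611 with an estimated correlation), a call lost without Emu-Myc 2 (0.0807), Emu-Myc 3 (0.0805), Gcn5 Fx/Fx 2 (0.14) or Gcn5 Fx/Fx 3 (0.0857). Ribosome biogenesis had 2 lower of 39 (1 adjusted over the list alone, median -0.07, camera adjusted p = 0.0373 and adjusted p = 0.649 with an estimated correlation), and its call was lost with total-count scaling (0.139), with a block for the replicate number (0.0521) and without Emu-Myc 2 (0.0807), Emu-Myc 3 (0.266), Gcn5 Fx/Fx 2 (0.333), WT 1 (0.0535), WT 2 (0.0624) or WT 3 (0.0591). Cytosolic ribosomal proteins had 4 higher and 1 lower of 78 (2 and 1 adjusted over the list alone) and a median of 0.20 (camera adjusted p = 9.59e-06 and adjusted p = 0.648 with an estimated correlation). A term for Emu-Myc 1, Emu-Myc 2 and WT 1 left 2 higher and 1 lower (median 0.14, camera adjusted p = 0.00417), and without these libraries the median was 0.21. With the term for Emu-Myc 1, Emu-Myc 2 and WT 1, nucleotide synthesis had 13 lower (median -0.33, camera adjusted p = 4.05e-08), amino acid and one-carbon metabolism 10 (-0.28, 8.77e-06), ribosome biogenesis 3 (-0.14, 0.000276) and chaperones 3 (-0.22, 0.000118). Without these libraries they had 8 (-0.37, 8.92e-07), 6 (-0.32, 1.45e-05), 2 (-0.14, 0.00325) and 6 (-0.30, 8.92e-07). Oxidative phosphorylation, mitochondrial ribosomal proteins and aminoacyl-tRNA synthetases, not past the threshold over all libraries (camera adjusted p = 0.0751, 0.387 and 0.296), passed with the term (medians -0.21, -0.16 and -0.15, camera adjusted p = 5.78e-06, 0.000148 and 0.00776) and without these libraries (-0.21, -0.14 and -0.16, 4.74e-05, 0.0014 and 0.00929). With an estimated correlation 0 of the 39 lists passed in either setting, with a smallest adjusted p of 0.382 with the term and 0.351 without these libraries.

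The erythroid list had 3 lower of 10 (6 adjusted over the list alone, median -2.38, camera adjusted p = 0.0007 and adjusted p = 0.501 with an estimated correlation), among them Tfrc, the transferrin receptor that dividing cells of other types also carry, at -0.83. T cell genes had 0 of 23 past the threshold (0 adjusted over the list alone) with a median of -0.95 (camera adjusted p = 0.00565 and adjusted p = 0.648 with an estimated correlation), a call lost without Gcn5 Fx/Fx 1 (0.0991). Under edgeR, Cd2, Cd5, Cd8a and Trbc2, the T cell genes with the smallest adjusted p, had values from 0.0555 to 0.164. NK cell genes had 1 higher of 11 (1 adjusted over the list alone), Prf1 (perforin), and a median of -2.01 (camera adjusted p = 0.0373 and adjusted p = 0.648 with an estimated correlation). With a term for Emu-Myc 1, Emu-Myc 2 and WT 1, the camera adjusted p was 0.37 for T cells (median -0.13), 0.606 for NK cells (-0.57) and 0.0568 for erythroid cells (-0.77), and without these libraries it was 0.264 (-0.30), 0.624 (0.16) and 0.102 (-0.14). The NK call was also lost without Emu-Myc 2 (0.188), Gcn5 Fx/Fx 1 (0.0551), Gcn5 Fx/Fx 3 (0.0687) or WT 1 (0.0548). The interferon response list had 5 higher of 25 (6 adjusted over the list alone, median 0.35, camera adjusted p = 0.00189 and adjusted p = 0.603 with an estimated correlation), with the GTPase Gbp3 at 0.76, and its call ended with that term (median 0.11, 0.543) and without these libraries (0.10, 0.731). Over all libraries the remaining lists were not past the threshold, with camera adjusted p from 0.0751 (oxidative phosphorylation, 2 lower of 37 and 1 adjusted over the list alone) to 0.93 (immediate early genes, median 0.05, mean -0.08). Sex-linked genes also passed without these libraries (0.000267, and 0.351 with an estimated correlation). There the medians of neutrophils (from -1.07 to 2.17), dendritic cells (-0.83 to 1.19), megakaryocytes (-1.82 to 0.41) and germinal centre B cells (-0.09 to 0.55) changed sign without passing. With the term these 4 medians were 2.08, 0.06, 0.24 and 0.08, and those of the pan-B list (-0.06 to 0.01) and of marginal zone and B1 cells (0.16 to -0.02) also changed sign. Glycolysis had 4 higher and 3 lower of 19 (6 and 5 adjusted over the list alone), a median of -0.12 and a mean of 0.05. The SAGA and ATAC list had 1 higher and 4 lower of 31 (1 and 4 adjusted over the list alone), of which Kat2a had the smallest adjusted p.

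The series title concerns Gcn5 and the genes that Myc induces, which is the overlap of the 2 comparisons above. Of the 4340 genes higher in Emu-Myc than WT, 799 (18.4%) were lower in Gcn5 Fx/Fx than Emu-Myc, and these made up 72.8% of the 1098 lower genes. Independent lists of these sizes would share 295.5 genes. Of the 799, 488 were still higher in Gcn5 Fx/Fx than in WT. In the opposite pattern, 862 of the 3626 genes lower in Emu-Myc (23.8%) were higher in Gcn5 Fx/Fx, against 275.8 for independent lists, and 377 of them were still below WT. Genes higher in both comparisons numbered 67 and those lower in both 22, against 330.2 and 246.8. The overlap of 799 fell to 491 with total-count scaling, to 209 without Emu-Myc 2, to 255 without Gcn5 Fx/Fx 1 and to 386 without Gcn5 Fx/Fx 3, and the opposite overlap of 862 to 382 without Emu-Myc 2 and to 441 without Gcn5 Fx/Fx 1. With Emu-Myc 1, Emu-Myc 2 and WT 1 left out these overlaps were 671 and 523, and with the term for them 940 and 708.

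The 10 genes of the first pattern with the smallest adjusted p over both comparisons were Sox4, Kat2a, Fam53b, Gclc, Rag2, Tmem132e, Otub2, Reln, Chchd10 and Sept11. Gclc, the catalytic subunit of the enzyme that opens glutathione synthesis, went from 44.7 ± 1.33 CPM in WT to 99.6 ± 8.08 CPM in Emu-Myc and 58.2 ± 3.07 CPM in Gcn5 Fx/Fx (SD, n = 3). Reln, an extracellular matrix protein, went from 10.4 ± 2.05 to 49.1 ± 0.78 and 18.5 ± 2.95 CPM. Those of the opposite pattern were Il9r, Rogdi, Pglyrp2, Gimap8, Trim7, Ank, Map3k5, Ift140, Gpr183 and Bcl2. Gimap8, of a GTPase family of lymphocytes, went from 334 ± 20.5 CPM in WT to 55.4 ± 5.86 CPM in Emu-Myc and 125 ± 7.26 CPM in Gcn5 Fx/Fx. Bcl2 went from 143 ± 15.4 to 52.3 ± 2.78 and 116 ± 13.1 CPM. The larger edgeR adjusted p of the 2 comparisons was at most 0.00124 for these 20 genes.

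Both comparisons use the Emu-Myc libraries with opposite sign, so their chance values oppose each other. Over all genes, which are not independent replicates, the fold changes had a correlation of -0.472, and 20 simulations of unchanged groups that shared the Emu-Myc libraries gave -0.499 on average. The covariance was -0.491 against -0.0712 in the simulations. The largest overlap in either opposite pattern was 0 genes in the simulations under the same edgeR test. Groups simulated without any change give few calls to overlap, so this 0 does not tell how much of the observed overlaps comes from the shared libraries. The 3 Emu-Myc libraries cannot be split between the comparisons with 2 or more on each side, so part of the excess over independent lists may come from the shared libraries. With 1 Emu-Myc library kept out of the search for Myc-higher genes and used alone as the reference for Gcn5 Fx/Fx, these genes had a median log2 difference of -0.04 for Emu-Myc 1, -0.17 for Emu-Myc 2 and -0.21 for Emu-Myc 3. For all genes the medians were -0.015, -0.007 and -0.009.

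**Figure D4:**
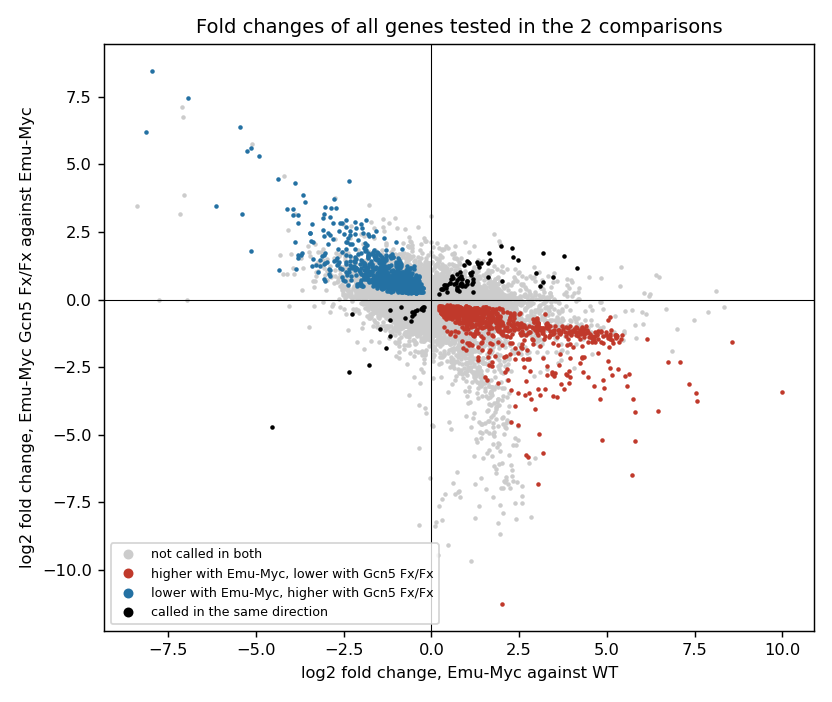
Log2 fold changes of the 16129 genes tested, Emu-Myc against WT (horizontal) and Gcn5 Fx/Fx against Emu-Myc (vertical), 1 point per gene. The 799 genes higher then lower lie at lower right, the 862 lower then higher at upper left, and the Emu-Myc libraries enter both axes with opposite sign.

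The comparison of Gcn5 Fx/Fx with WT shows what remained different from normal B cells. Growth and cell cycle genes stayed high, mature B cell and NF-kB genes stayed low, and early B cell genes as a list did not pass the threshold. None of these lists was called by camera with an estimated correlation. Smyd2, a lysine methyltransferase, rose 24.5-fold to 58.9 ± 7.65 CPM from 2.40 ± 0.62 CPM (SD, n = 3), and Car12 stood at 13.0 ± 0.41 against 0.16 ± 0.07 CPM. Top2a held 270 ± 119 CPM against 22.8 ± 0.99 CPM, and Fcer2a was at 157 ± 33.3 against 708 ± 97.8 CPM. The edgeR adjusted p-values of these 4 genes were at most 3.21e-05.

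The test called 4091 genes higher and 3222 lower (45.3% of 16129), of which 1741 and 1272 changed at least 2-fold. Scaling by total counts moved the median of all genes by -0.14 and gave 3178 higher and 4359 lower genes, a share of higher calls of 42.2% against 55.9%. Of the 4340 genes higher in Emu-Myc than WT, 3407 (78.5%) were also higher here, against 1101 for independent lists. Of the 3626 lower genes 2304 (63.5%) were also lower, against 724.3. With the term for Emu-Myc 1, Emu-Myc 2 and WT 1 the test called 4187 and 3208 genes (3934 and 2902 shared), and without them 3945 and 2842 (3633 and 2533 shared). The fold changes against WT had a covariance of 0.877, and 0.0715 in simulations of unchanged groups that shared the WT libraries, whose correlation was 0.501 beside 0.691 observed. Part of this overlap may come from the shared WT libraries, which cannot be split either. The largest rises were Car12 (6.28, SE 0.29), Dnph1, the adenylate kinase Ak7, Ltbp4, the synaptic adhesion protein Nlgn2, Hist1h2ah, the actin nucleator Spire1, Smyd2, Ankrd13b and Hspa12b (4.44, SE 0.47), with edgeR adjusted p up to 8.05e-05. The largest falls were Mertk (-5.14, SE 1.66), C1qb, Vcam1, C1qc, Ccr3, C1qa, Cd163, Abcc3, Itgad and Sema6d (-4.37, SE 1.38), with edgeR adjusted p up to 0.0478. Of these 10 calls, 10 were lost without WT 1 (adjusted p up to 0.334), the WT library with 425 CPM of macrophage genes, 10 without Gcn5 Fx/Fx 1 (0.134) or Gcn5 Fx/Fx 3 (0.128), 9 without Gcn5 Fx/Fx 2 (0.0876) and 1 without Emu-Myc 1 (0.0606), all by edgeR. Their log2 fold changes shrank without WT 1, to -2.88 (C1qb) to -1.90 (Sema6d), and lay from -6.03 (Cd163) to -4.00 (Itgad) in the other cases. With limma-voom all 10 were lost (adjusted p from 0.24 to 0.401), with log2 fold changes from -4.14 (C1qb) to -3.16 (Sema6d), and Cd163 also with the term for Emu-Myc 1, Emu-Myc 2 and WT 1 (edgeR adjusted p = 0.0744) and without these libraries (0.0554). The 10 falls were smaller in these 2 settings, at -2.68 (C1qb) to -1.76 (Cd163) with the term and -2.88 (C1qb) to -1.89 (Sema6d) without these libraries.

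Protein synthesis lists stayed high in Gcn5 Fx/Fx. Ribosome biogenesis was higher in 39 of 39 genes (39 adjusted over the list alone, median 1.09, camera adjusted p = 1.36e-19 and adjusted p = 0.172 with an estimated correlation), cytosolic ribosomal proteins in 75 of 78 (76, median 1.23, 2.9e-27, 0.268) and translation factors in 25 of 26 (25, median 0.89, 3.9e-12, 0.175), with values in the same order. In that order, aminoacyl-tRNA synthetases had 18 higher and 1 lower of 20 (19 and 1, median 0.51, 2.75e-06, 0.339), mitochondrial ribosomal proteins 42 higher of 45 (43, 0.65, 3.5e-12, 0.323), nucleotide synthesis 26 of 27 (26, 1.25, 3.5e-12, 0.257) and amino acid and one-carbon metabolism 24 of 26 (25, 1.23, 7.69e-12, 0.175). Chaperones had 21 of 27 (22, 0.92, 2.63e-09, 0.175), oxidative phosphorylation 37 of 37 (37, 0.75, 2.67e-12, 0.339) and glycolysis 13 higher and 1 lower of 19 (14 and 1, 1.02, 8.71e-06, 0.175). Npm1 stood at 1438 ± 31.9 against 379 ± 11.3 CPM and Phgdh at 301 ± 11.7 against 70.3 ± 3.24 CPM (SD, n = 3).

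Cell cycle lists were also above WT. Mitosis genes were higher in 34 of 39 cases (34 adjusted over the list alone, median 3.01, camera adjusted p = 6.13e-12 and adjusted p = 0.414 with an estimated correlation). With values in the same order, DNA replication had 28 higher and 1 lower of 38 (31 and 1, 1.08, 1.04e-07, 0.496), G1/S and E2F genes 19 and 2 of 24 (19 and 2, 1.16, 1.42e-05, 0.339), histones 25 and 0 of 28 (25, 1.70, 1.6e-10, 0.307), p53 targets 15 and 3 of 26 (15 and 3, 0.44, 0.00667, 0.172) and the MYC network 8 and 1 of 15 (8 and 2, 0.32, 0.0333, 0.189). The strict filter on low counts ended the camera calls of p53 targets (adjusted p = 0.0544) and the MYC network (0.06). Mature B cell genes were lower in 27 of 29 cases (27 lower and 1 higher adjusted over the list alone, median -0.73, camera adjusted p = 1.21e-10 and adjusted p = 0.172 with an estimated correlation), such as the interleukin 4 receptor Il4ra from 576 ± 58.5 to 159 ± 11.2 CPM (SD, n = 3). Again in that order, NF-kB targets had 1 higher and 14 lower of 17 (1 and 14, -0.70, 9.02e-06, 0.257), the pan-B and B cell receptor list 2 and 13 of 25 (2 and 13, -0.35, 0.000525, 0.172) and MHC class II 0 and 7 of 21 (0 and 5, -0.25, 0.00741, 0.549). The pro-B and pre-B list had 6 higher of 19 (5 adjusted over the list alone, median 0.41, camera adjusted p = 0.128), and macrophages and monocytes 1 higher and 8 lower of 19 (1 and 8 adjusted over the list alone, median -2.76, 0.0625). With the term for Emu-Myc 1, Emu-Myc 2 and WT 1 the macrophage list passed (median -0.96, camera adjusted p = 0.022, and 0.607 with an estimated correlation), as it did without these libraries (-1.23, 0.0166, and 0.559 with an estimated correlation). Over all libraries the other lists had camera adjusted p from 0.06 (T cells) to 0.881 (neutrophils), and of these the interferon response list (0.149) passed with the term (-0.74, 0.0071, and 0.419 with an estimated correlation) and without these libraries (-0.62, 0.0166, and 0.559 with an estimated correlation). Neutrophils went from a median of -0.31 to 1.93 with the term and 1.82 without these libraries, dendritic cells from -0.69 to 0.42 with the term, stroma and endothelium from -0.15 to 0.37 with the term, and sex-linked genes from -4.17 to 0.11 without these libraries, none past the threshold.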

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

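The term for Emu-Myc 1, Emu-Myc 2 and WT 1, the fits without these 3 libraries and the counts without antigen receptor segments were chosen after the results were seen. The Kat2a log2 fold change between Emu-Myc Gcn5 Fx/Fx (below, Gcn5 Fx/Fx) and Emu-Myc kept its direction and its call in all 19 alternatives, from -0.81 to -0.69 (adjusted p from 1.045e-15 to 0.00845 by edgeR, DESeq2 or limma-voom), and from -0.78 to -0.69 when each library was left out.

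Requiring a log2 fold change of at least 1 lowered counts by construction, to 2005 higher and 1507 lower genes (Emu-Myc against WT), 382 and 484 (Gcn5 Fx/Fx against Emu-Myc) and 1741 and 1272 (Gcn5 Fx/Fx against WT), with 300 genes higher then lower across the first 2 comparisons and 226 lower then higher. With total counts in place of TMM the 799 genes higher then lower became 491, where the scale of all genes had moved. Without Emu-Myc 1, Emu-Myc 2 and WT 1, which leaves 6 libraries, 621 genes were higher in Gcn5 Fx/Fx than Emu-Myc and 523 were lower then higher. The NK cell list (camera adjusted p = 0.624), Nkg7 (log2 fold change 0.0398) and Hba-a2 (0.249) also changed direction there between Gcn5 Fx/Fx and Emu-Myc, as did the medians of lists not called: neutrophils (from -1.07 to 2.17), dendritic cells (-0.83 to 1.19), megakaryocytes (-1.82 to 0.41) and germinal centre B cells (-0.09 to 0.55). With the term these 4 medians changed sign too (2.08, 0.06, 0.24 and 0.08). For Emu-Myc against WT the medians of NK cells (0.63 to -1.03), dendritic cells (0.75 to -0.86), erythroid cells (1.30 to -0.47) and megakaryocytes (0.05 to -1.76) changed sign without these libraries. The cause was not tested.

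Leaving out each library gave 3825 to 4434 higher and 2830 to 3651 lower genes for Emu-Myc against WT, 473 to 1578 and 267 to 1453 for Gcn5 Fx/Fx against Emu-Myc, and 3602 to 4191 and 2342 to 3303 for Gcn5 Fx/Fx against WT. The overlaps ran from 209 to 1111 (higher then lower) and from 382 to 1091 (lower then higher). The lowest values of the second comparison and of both overlaps were without Emu-Myc 2 and the highest without WT 1.

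Whether the replicate numbers pair the libraries was not clear. A correlation of deviations above 0.1 was found in 4 of 9 pairs with the same number (range -0.316 to 0.403) and in 6 of 18 with different numbers (-0.513 to 0.469). As a block the replicate numbers gave 1171 lower genes between Gcn5 Fx/Fx and Emu-Myc and overlaps of 862 and 826.

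Of 344 results for named genes, limma-voom made 25 weaker and 2 stronger, DESeq2 made 8 stronger, the term made 11 weaker and 3 stronger, and the fits without the 3 libraries made 22 of 343 weaker. Leaving out each library in turn made 177 of 3096 such results weaker and 18 stronger. Calls lost numbered 45 without Gcn5 Fx/Fx 1, 35 without Gcn5 Fx/Fx 3, 35 without Emu-Myc 2 and 23 without Gcn5 Fx/Fx 2, and 3 to 12 without each other library. Of 62 list calls, fry lost 9 and the estimated correlation lost 62. The 9 lost under fry were all between Gcn5 Fx/Fx and Emu-Myc. By fry adjusted p they were macrophages (0.0596), amino acid and one-carbon metabolism (0.0697), translation factors (0.0954), interferon response (0.11) and nucleotide synthesis (0.115). The others were ribosome biogenesis (0.184), cytosolic ribosomal proteins (0.204), T cells (0.283) and NK cells (0.337). With few genes changed, simulated changes of 1.5-fold were called in 24.2% to 25.7% of cases and of 2-fold in 44.4% to 61.4%, and depth was not varied.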

Other observations

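All tests of explanations here except the counts over other splits of the libraries were chosen after the result was seen.

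Macrophage and monocyte genes were high in Emu-Myc 1, Emu-Myc 2 and WT 1 and lower in Emu-Myc Gcn5 Fx/Fx (below, Gcn5 Fx/Fx) than in Emu-Myc. The log2 excess of Emu-Myc 1 and 2 over Emu-Myc 3 was compared with that of WT 1 over the other WT libraries. Across the listed genes, which are not independent replicates, these correlated (Pearson r = 0.981, with an excess in both for 18 of 19). RNA of 1 cell type could give this, but so could any rise shared by these libraries. Among these 18 genes the excess in Emu-Myc ran from 2.03 CPM (Fcgr1) to 147 CPM (Vcam1), so r does not decide. The ratio of the excess in Emu-Myc to that in WT ran from 1.27 (Lyz2) to 3.40 (Slc40a1). Vcam1 had 147 and 67.8 CPM, Csf1r 132 and 50.3 CPM and Axl 95.5 and 34.03 CPM of excess in Emu-Myc and in WT. A sort on CD19 would remove macrophages, no other list holds these genes, and 8 of 19 reached 1 CPM in every Gcn5 Fx/Fx library. A fit of all 9 libraries with a term for these 3 libraries and a term for sex gave a median of -1.87 (camera adjusted p = 4.45e-09). With an estimated correlation the list was not called there (adjusted p = 0.429) or without the terms (0.501). This fit does not decide whether the 3 libraries are the whole cause of the lower levels in Gcn5 Fx/Fx. The 1 Emu-Myc library outside them is male and WT 1 is male too. The 2 terms therefore separate only if both shifts are equal in Emu-Myc and WT on the log scale of the fit. On that scale the list's mean was 4.65, 5.18 and 1.59 in Emu-Myc 1 to 3. In WT 1 to 3 it was 3.88, 0.83 and 1.34. Sex differs between the same libraries, so these values do not show whether the shifts were equal. An effect of the Gcn5 genotype cannot be told apart from Cre or the sort, and 2 measures differ, since the lowest mean log2 CPM of the list outside Gcn5 Fx/Fx lay 0.15 above the highest within it, while by summed CPM Gcn5 Fx/Fx 2 (80.3) lay above WT 2 and WT 3 (50.7 and 69.2) and Gcn5 Fx/Fx 1 (51.5) above WT 2.

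Of 116 Ighv segments tested (heavy chain variable gene segments), only called ones past a cut on fold change were taken, as blocks. The block low in Gcn5 Fx/Fx had 23 segments, with log2 fold changes against Emu-Myc from -11.26 to -2.11. Summed, they were at 48.1 CPM in Emu-Myc and 0.622 CPM in Gcn5 Fx/Fx. The block low in Emu-Myc had 33, from 2.11 to 8.46 (40.4 against 353 CPM). Some segments lay near the floor in both groups, such as Ighv8-2 (at most 0.19 CPM). WT 3 lay outside both other WT libraries on the side of its block for 55 of the 56 segments (98.2%), as heavy chain loci of different strain origin could give, although the labels name 1 strain. No share by chance is given, since WT 3 was picked after the values were seen and the segments lie together in 1 locus. The largest share of Ighv counts on 1 segment was 9.05%, in Gcn5 Fx/Fx 3, against 4.6% to 5.69% in the other libraries. Among the segments counted, this argues against 1 clone making up most of a library. A segment that was not counted would not enter the share, so a clone using such a segment is not excluded. Summed Ighv levels were 375 to 408 CPM in Emu-Myc and 656 to 936 CPM in the other libraries. The share does not decide on smaller clones. In Gcn5 Fx/Fx 3, 1 segment was at 71.46 CPM, against 19.38 and 18.19 CPM in its replicates. Light chain segments were not part of this test, and 1 of them, given below, was higher in Emu-Myc than in all other libraries. Segments resemble each other, and how shared reads were counted is not stated.

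Pro-B and pre-B genes were lower in Gcn5 Fx/Fx than in Emu-Myc. Whether Emu-Myc 1, Emu-Myc 2 and WT 1 made this difference was not decided. The same fit with 2 terms gave a median of -1.66 (camera adjusted p = 5.75e-07). With an estimated correlation the list was not called there (adjusted p = 0.429) or without the terms (0.369). Its 2 terms separate only if both shifts are equal in Emu-Myc and WT. Without these libraries the list's median was -1.97, so the fall was no smaller than the -1.69 over all libraries. That fit does not decide either, since it rests on 1 Emu-Myc library and confounds sex with genotype. This library is male and the others in the fit are female by Y-linked genes. Fewer immature B cells would leave each gene the same share of its excess over WT. Of the 11 called members, Il7r (-20.6%) and Cd24a (-17.9%) lay below WT, and the others kept 4.13% (Cd93) to 14.5% (Dntt). The SD of the share between genes was 1.17 times the median SD within genes. The first is an SD of means over 3 libraries and the second of single libraries, so this ratio does not decide. Fewer such cells and lower expression per cell cannot be told apart, and either may hold.

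The 10 splits of 6 libraries are too few for a share under 0.05. For Emu-Myc against WT, 1 of 10 splits, the real one, gave 7966 calls, and the highest other gave 78, with Emu-Myc 1, Emu-Myc 2 and WT 1 on 1 side. The real and highest other values were 2325 and 2 for Gcn5 Fx/Fx against Emu-Myc, 7313 and 0 for Gcn5 Fx/Fx against WT, and 799 and 1 for genes higher then lower.

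Genes called between Gcn5 Fx/Fx and Emu-Myc made up 18% of the 267 tested within 10 Mb of Kat2a, against 13.8% elsewhere (Fisher's exact adjusted p = 0.216), and 16.3% of 209 near Cd19 (0.709). Of 234 windows of 10 Mb, the one with the smallest adjusted p lay at 20 to 30 Mb of chromosome 13, with 48 of 97 genes called (Fisher's exact adjusted p = 1.34e-14), where the Hist1 genes lie. Il9r (chromosome 11, 32187541 to 32200279) and Rhbdf1 (32209585 to 32222300), both higher in Gcn5 Fx/Fx, are neighbours. Igkv1-88, a light chain segment, was at 182 to 243 CPM in Emu-Myc and at 4.66 to 8.67 CPM in the other libraries. Ighd, the constant region of IgD, was at 334 to 483 CPM in Emu-Myc, 855 to 1151 CPM in Gcn5 Fx/Fx and 1856 to 2085 CPM in WT. These genes were singled out after their values were seen. The CPM of Igkv1-88, Ighd and Ddx3y in this paragraph are scaled by total counts, without TMM. The Y-linked gene Ddx3y was at 102 CPM in Emu-Myc 3 and 125 CPM in WT 1 and at most 0.04 CPM elsewhere, so the sexes are mixed within these groups.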
